A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

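The series holds 8 microarrays of E. coli K-12, each hybridised with RNA from pH 5 cells in one dye and RNA from pH 7 cells in the other. Per the labels' protocols, cells growing exponentially at 37 °C were moved to minimal medium at pH 5 or pH 7, with or without 5.4 µM cadmium, and held at 25 °C for 5 or 15 minutes. Each of the 4 conditions (cadmium or none, 5 or 15 minutes) has 2 arrays. On the forward array (replicate 1 here) Cy5 marks pH 5, and on the dye-swapped array (replicate 2 here) Cy5 marks pH 7. The replicate numbers were given here in the order of the records. The design text names 2 overnight cultures as biological replicates and dye swaps for each of them, which 8 arrays cannot hold in full if each swap was a further array. The 2 arrays of a condition were treated as replicates. If a swap reused the RNA of its forward array, the p-values measure technical spread.

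The deposited spot files hold intensity values made with TIGR Spotfinder 3.1.1, per the file headers. They give the mean intensity of a spot in channels A and B, with no background subtracted, and the median local background. Spots that failed the software's quality filter hold 0. The header text is the same in 5 of the 8 files, so scan records could not serve as batches. The deposited table of the authors' processed values was taken as log2 ratios. Its correlation with the spot files does not show the base, and the counts drawn from it do not depend on the base. Its rows carry no gene names. Per the series' design text, the authors normalised by a regional lowess in R 2.4.1, took medians over triplicate spots and fitted a mixed model per time point. How they centred the deposited table is not given in the sources used here. The medians of its 8 columns were 0.567, -0.136, 0.182 and 0.223 for the forward arrays and 0.0183, 0.216, -0.630 and -0.162 for the swapped arrays, in each case in the order cadmium 5 minutes, no cadmium 5 minutes, cadmium 15 minutes, no cadmium 15 minutes.

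Channel A was taken as Cy3 and channel B as Cy5. This is likely and not certain: the image numbering in the headers follows the channel order of the labels, while no header names a dye. The image lines belong to the header text that 5 of the 8 files share, so they need not describe each array's own scan. The deposited table runs as A over B on forward arrays, so under this assignment it runs as pH 7 over pH 5 there, opposite to the direction used here. If the channels are the other way round, every sign of a pH effect, an interaction or a difference between times turns. The cadmium contrasts do not depend on it.

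Gene names were not used in the order in which the files pair them with spots. Under that order the blank spots, which should be dark, exceeded the filter at a median of 16.9% over arrays, and ribosomal protein genes lay at a median brightness percentile of 49.7. After the files were seen, 13 orders of the names were compared: as listed, mirrored, reversed as a whole, reversed within print blocks and shifted within blocks. Reversing the whole grid gave 0.930% of blank spots above the filter and a ribosomal percentile of 71.2. The next highest ribosomal percentile was 59.1. The 3 other orders reversed within blocks gave the same blank value, so the blank spots fix the order within blocks and not the order of the blocks. The block order rests on the brightness of abundant genes, which was also used to choose it. Both tests that were written down before their results left the choice open, as given in the closing section. All gene names below carry this limit. Triplicates stay together under either order, so another order would exchange names. The numbers of tests change where names fall on blank, unnamed or dim spots. With genes missing on some arrays kept, 2481 genes could be fitted in the chosen order and 1988 in the listed one. Of 3988 distinct names, 3768 matched a symbol or older symbol in the reference table of assembly ASM584v2, which gave 3749 symbols. That table was used for names and for neighbouring genes only.

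Background was corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), since the files hold uncorrected values. Spots at 0 in either channel or marked bad by the image software were left out. No spot above the filter was marked bad. Log ratios were normalised within each array by a joint loess on mean log intensity, slide row and slide column (degree 1, span 0.3), with control spots left out of the fit. The median over the spots of a gene was then taken. A gene entered a fit when it had a value on every array of that fit, a rule set after the files were seen. This left 809 genes on all 8 arrays, 2146 on the 4 arrays of 5 minutes and 905 on the 4 arrays of 15 minutes.

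Tests were run with limma on log2(pH 5 / pH 7), with lmFit and eBayes. The pH effect and the interaction of pH and cadmium were fitted at each time point from 4 arrays without a dye term. A dye bias of equal size in both orientations then cancels in the mean and stays in the residual, which makes these p-values conservative. Where 1 array is left out, its condition keeps a single orientation and the bias stays in the pH estimate. The average pH effect and the difference between times came from all 8 arrays with 1 coefficient per condition and a dye coefficient per gene. Cadmium effects lie between arrays and were fitted on single channels after Aquantile normalisation (lmscFit with the correlation within spots from intraspotCorrelation, which uses statmod 1.5.0). In fits of 3 arrays that correlation could not be estimated, and the value of the full fit was used. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. There were 9 comparisons. In addition, 30 gene lists with 483 genes were tested with camera (preset correlation 0.01) beside camera with an estimated correlation and fry, where at least 3 members were measured. With an estimated correlation, camera takes its degrees of freedom from the few arrays of a fit. Hardly any list could pass that version, whatever its correlation. Where the members of a list correlate more than the preset, the p-values of the preset version are too small. For cadmium the list tests used mean log intensities per array. Besides the lists, 26 single genes were fixed.

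The tests, the lists, the 26 genes and the alternatives were chosen before the data were examined, except where stated. Named genes are, per comparison, the 10 largest changes each way among genes past the threshold. Where fewer than 5 passed in a direction, up to 5 of those with the smallest unadjusted p are given as values. Up to 4 members per list and the 26 fixed genes are named too. Alternatives covered background correction, normalisation, spot summary, dim genes, spot marks, single arrays left out, dye terms, the variance model, the authors' processed values and the correlation within lists. After seeing the data, 3 more were added: names in the listed order, genes missing on some arrays kept, and both dye-swapped cadmium arrays left out.

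The functions were tested on simulated data with 200 changed genes at the observed spread of the log ratios. Of the genes simulated with a log2 change of 2, the average pH effect recovered 97.1%, the pH effect 23.3% at 5 minutes and 40.3% at 15 minutes, and the difference between times 69.7%. False calls were 12, 0, 2 and 5. Each simulated gene had the same spread on every array and a dye bias of equal size in both orientations. The real arrays had log ratio SDs from 0.67 to 2.20. These pH shares are therefore optimistic too, and a count of 0 does not exclude changes of that size. Both interactions, fitted on 4 arrays without a dye term, recovered 0 even at a log2 change of 4. The cadmium effects recovered 90.8% over all conditions, 82.7% at 5 minutes and 88.1% at 15 minutes, with 4, 20 and 20 false calls. Their noise was drawn independently per channel from the spread of the log ratios, which is optimistic. It did not use the spread between arrays, on which the cadmium effects rest. These shares therefore do not show which cadmium changes could be detected. In the data the median SE of the cadmium effect at 5 minutes was 0.92. Figures were drawn with matplotlib 3.10.9.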

Results

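Transcript levels of E. coli K-12 were measured on 8 oligonucleotide arrays after a shift to pH 5 or pH 7, without cadmium or with 5.4 µM cadmium, for 5 or 15 minutes. Cadmium is a toxic metal that cells export through zinc transporters, and the design asks how acidity and cadmium act together on transcription. Each of the 4 conditions had 2 arrays, 1 per dye orientation, and every array compared pH 5 with pH 7 directly. Each array carried 21168 spots, with 7056 features in triplicate. Signal differed widely: the share of spots above the quality filter ran from 21.1% on the dye-swapped cadmium array of 15 minutes to 82.9% on the dye-swapped array of 5 minutes without cadmium. The genes measured per array ranged from 1258 to 3704. The correlation of Cy3 with Cy5 intensities ran from -0.334 on that cadmium array to 0.758 on the forward array of 5 minutes without cadmium.

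All signed pH values are log2(pH 5 / pH 7) with channel B taken as Cy5. That assignment is likely and not certain, it runs against the direction of the deposited value table, and with the channels exchanged every pH sign turns. Gene names follow the spot order read from the opposite corner of the grid, chosen among 13 orders after the files were seen. Ribosomal protein genes, among the most abundant transcripts of growing cells, had a mean brightness percentile of 71.2 in that order and 49.7 in the listed one (medians over arrays). On the dye-swapped cadmium arrays they stayed at 44.4 (5 minutes) and 52.3 (15 minutes) in the chosen order. Tests not used in choosing the order left it open, so every gene name is provisional.

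**Figure D1:**
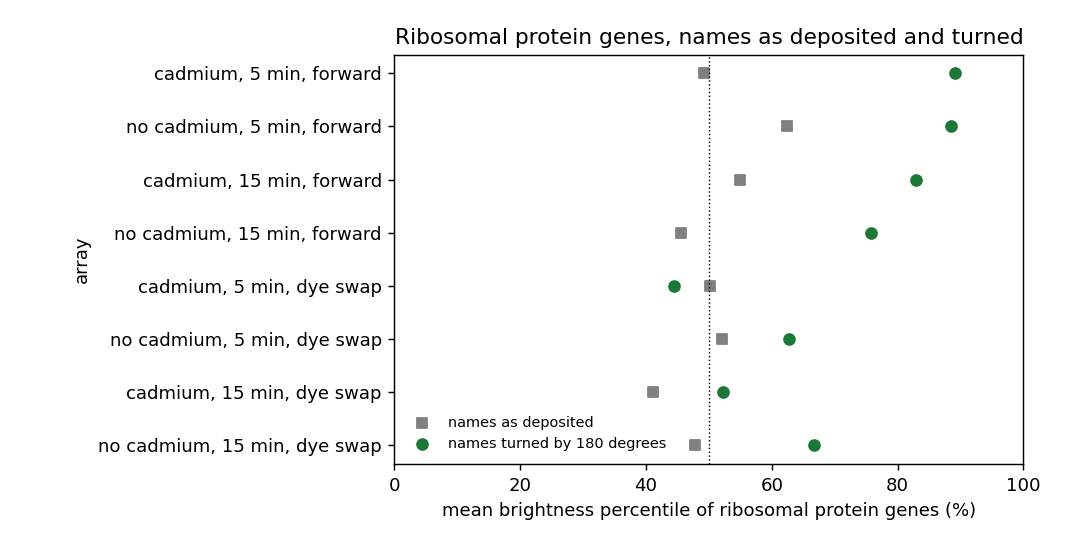
Mean brightness percentile of ribosomal protein genes (x axis, %) on each of the 8 arrays (y axis), with spot names as listed (squares) and in the chosen order (circles); the dotted line marks 50. Circles lie between 75.8 and 89.1 on the forward arrays and between 44.4 and 66.6 on the dye-swapped ones.

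The average over all 4 conditions asked which genes differ between pH 5 and pH 7 whatever the cadmium and time. Among genes measured on all 8 arrays, the smallest p-values belonged to nagZ, a glucosaminidase of cell wall recycling (log2 change 1.71 ± 0.18 SE, adjusted p = 0.105), fbaA, the glycolytic aldolase (1.42 ± 0.22), and cydB of the cytochrome bd oxidase (1.47 ± 0.24). Each of these lay on its side of 0 on only 4 of 8 arrays. malQ, the amylomaltase of maltodextrin use, had 0.78 ± 0.15 and was above 0 on 8 of 8 arrays, while hsdM, the methylase subunit of a restriction system, had 0.91 ± 0.19 and was above 0 on 4 of 8. On the other side stood pepB, an aminopeptidase, at -1.59 ± 0.34, the stress protein gene yhbO at -1.47 ± 0.32, the proline transporter gene putP at -0.64 ± 0.17, frvA of a sugar phosphotransferase system at -0.95 ± 0.26 and aroK, a shikimate kinase gene, at -1.82 ± 0.49. They were below 0 on 4, 4, 7, 5 and 6 of 8 arrays, in that order. None of the 809 genes passed in limma, and 66 had an unadjusted p under 0.05 (43 higher, 23 lower) where chance gives 40.5 (17 to 140 over the alternative settings). Some alternative settings fit other numbers of genes, so here and below the chance value holds for the reported fit only.

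Acid-stress genes were measured on too few arrays for most of these fits, so their values are given per array. asr, which encodes a periplasmic protein made on acid shock, was above 0 on 7 of the 7 arrays that measured it, with a mean of 2.26 ± 2.05 (SD). Its values ran from 0.56 on the swapped array of 5 minutes without cadmium to 6.31 on the forward cadmium array of 5 minutes. cpxP, an inhibitor of the Cpx envelope stress response, was below 0 on 6 of 6 arrays (mean -1.83 ± 1.98 SD). hdeA, an acid-activated periplasmic chaperone, ranged from -3.36 to 8.13, and the mean of its forward arrays was -1.56 against 3.87 for the swapped arrays. gadA of glutamate-dependent acid resistance was below 0 on 4 of 4 arrays (mean -0.28 ± 0.15 SD). Other genes fixed from the Gad and Hde list went the other way on most arrays. gadB was above 0 on 4 of 6 (mean 0.04 ± 1.09 SD), gadE on 3 of 4 (0.30 ± 0.96) and hdeB on 4 of 6 (0.13 ± 0.81). The gadB values above 0 were those of the swapped arrays (mean 0.64), and both forward values were below 0 (mean -1.16). Its sign thus went with the dye orientation. atpA of ATP synthase averaged -0.59 ± 0.32 (SD) and was above 0 on 1 of 7 arrays. In an alternative chosen after seeing the data, which kept genes missing on some arrays, asr had 2.55 ± 0.23 (SE) with an adjusted p of 0.122 in limma and ranked second among 2481 genes by p.

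**Figure D2:**
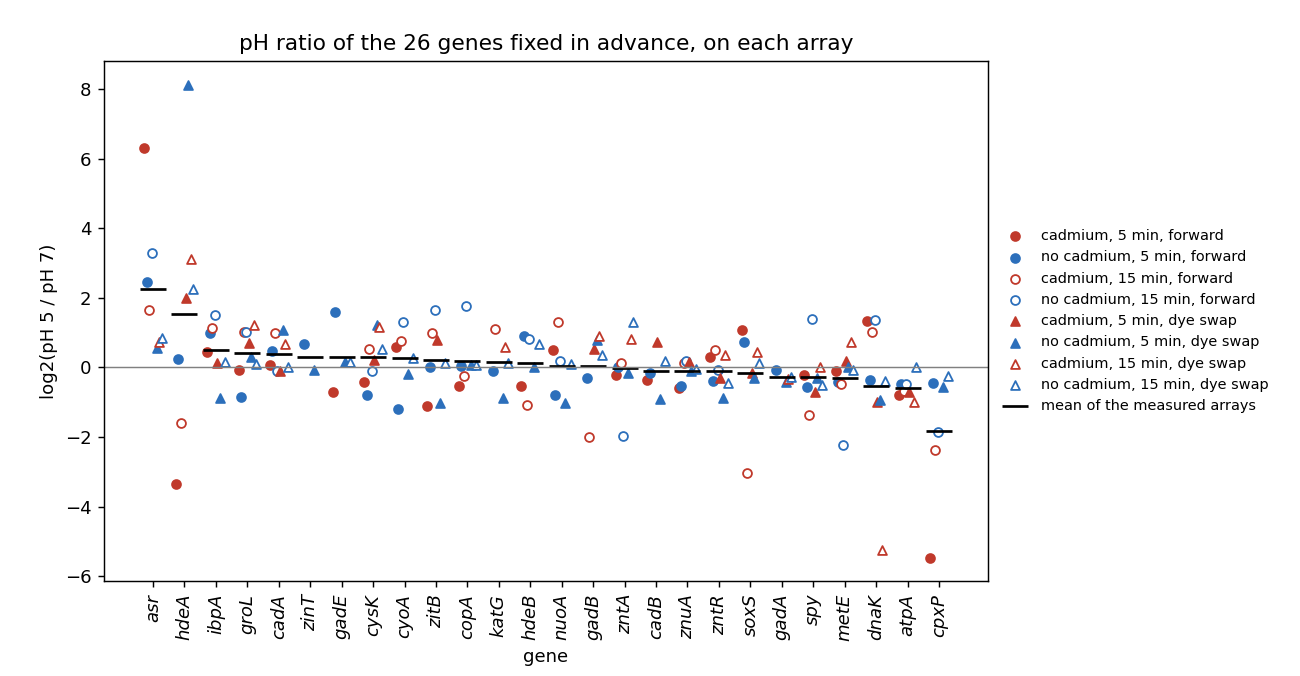
log2(pH 5 / pH 7) of the 26 genes fixed in advance (x axis) on each array that measured them (y axis); circles are forward and triangles dye-swapped arrays, filled at 5 minutes and open at 15 minutes, red with and blue without cadmium, and bars are means. asr lies above 0 on 7 of 7 arrays and cpxP below 0 on 6 of 6.

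Of the 18 gene lists with enough members, none passed for the average pH effect. The general stress list of the starvation sigma factor had 4 of 5 members above 0 (median 0.28) and the oxidative stress list 4 of 4 (median 0.28), each with an adjusted p of 0.361 in camera and 0.820 with an estimated correlation. Adjusted over the list alone, 1 member each of 5 lists passed: carB of arginine synthesis (-0.63 ± 0.19), cydB, the catalase gene katE (0.96 ± 0.23), the lysine decarboxylase gene cadA (0.38 ± 0.15, the only measured member of its list) and the potassium efflux gene kefC (1.31 ± 0.33). Over all 809 genes they did not pass for pH, and cydB, katE and kefC passed for the dye coefficient (Cy5 over Cy3 -4.56, -1.36 and -2.40). Arrays of the same dye orientation had pH ratios that correlated above 0 over genes in 12 of 12 pairs, and arrays of opposite orientation correlated between -0.66 and -0.18 in 16 of 16 pairs.

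**Figure D3:**
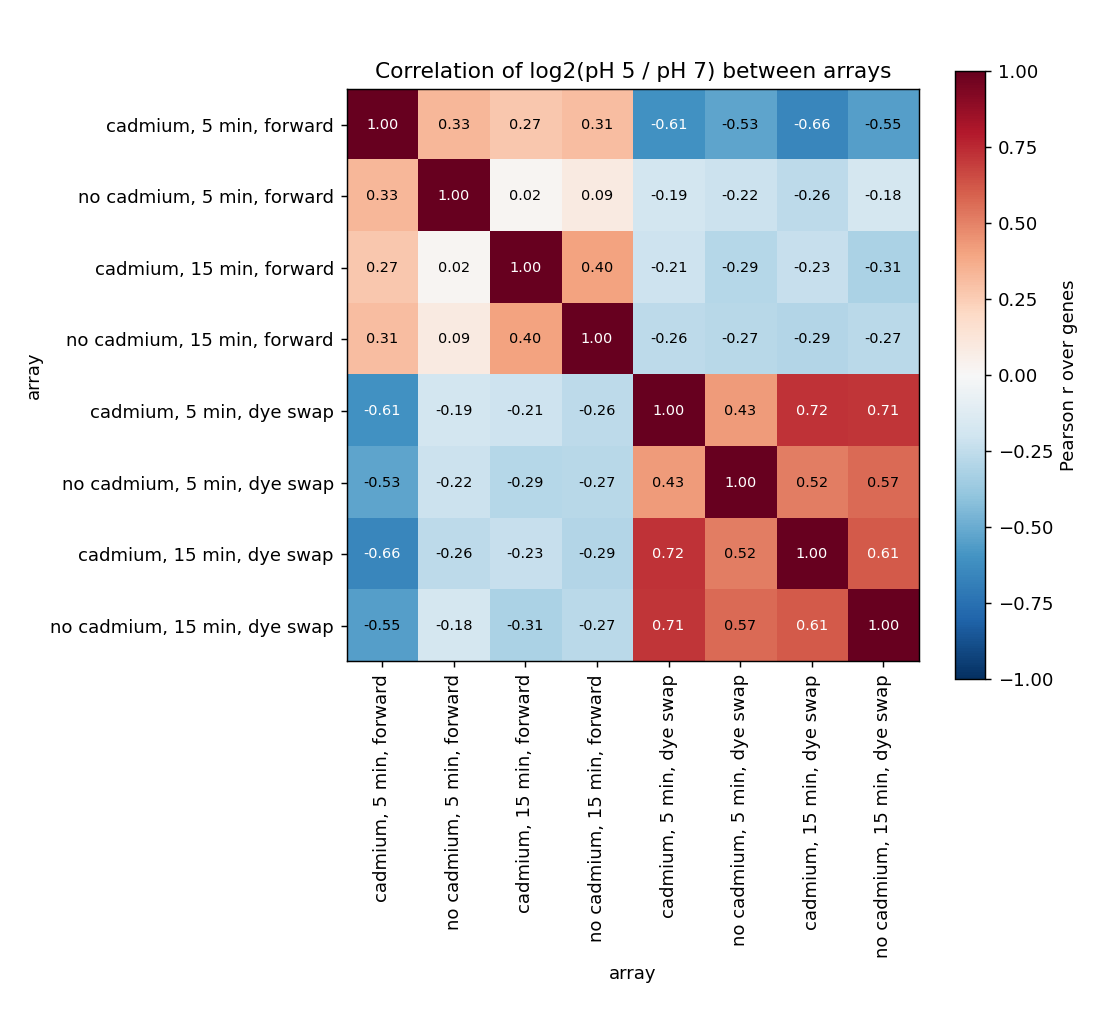
Pearson correlation over genes of log2(pH 5 / pH 7) between each pair of arrays (both axes list the 8 arrays; colour and printed values give r). Pairs of dye-swapped arrays lie between 0.43 and 0.72, pairs of forward arrays between 0.02 and 0.40, and pairs of opposite orientation between -0.66 and -0.18.

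The dye coefficient of the same fit passed for 108 of the 809 genes (51 brighter in Cy5, 57 in Cy3), with a median size of 0.36 against 0.21 for the pH effect. Of the 10 genes with the smallest p for pH, 7 also passed for the dye, among them nagZ (Cy5 over Cy3 -3.40), cydB (-4.56) and pepB (3.07).

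**Figure D4:**
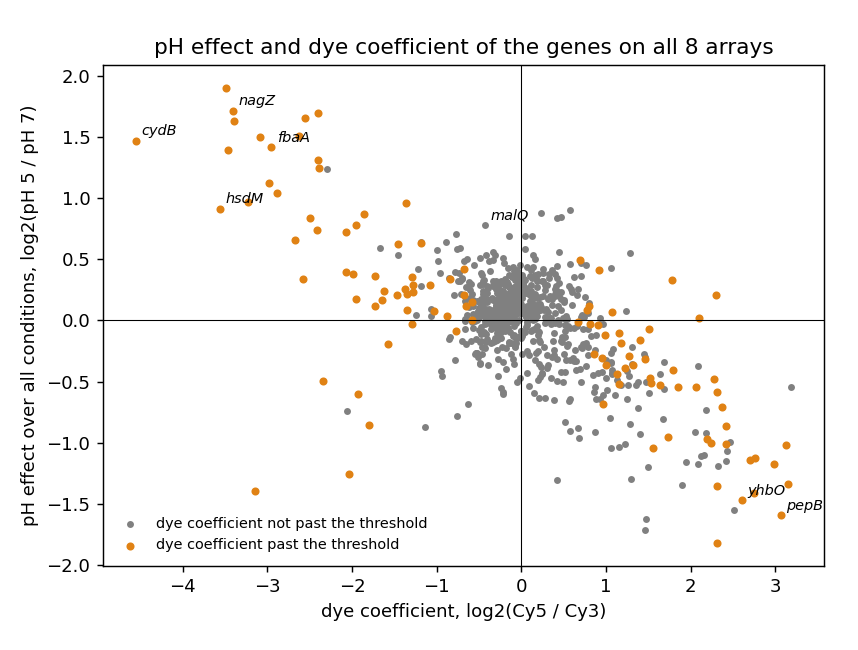
pH effect over all conditions, log2(pH 5 / pH 7) (y axis), against the dye coefficient, log2(Cy5 / Cy3) (x axis), for the 809 genes on all 8 arrays; orange points passed for the dye. The correlation over genes is -0.657.

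At 5 minutes the pH effect was sought in cells that had just met the acid medium. Genes of arginine biosynthesis fell as a list in camera (1 of 7 members above 0, median log2 change -0.41, adjusted p = 0.0131; adjusted p = 0.826 with an estimated correlation). carB, a subunit of carbamoyl phosphate synthetase, had -0.77 ± 0.30, argH, the argininosuccinate lyase, -0.78 ± 0.44, argC -0.35 ± 0.28 and argI, an ornithine carbamoyltransferase, -0.60 ± 0.53. Ribosomal protein genes also fell as a list, with 27 of 40 members below 0 and a median of -0.13 (mean -0.07, adjusted p = 0.0384; adjusted p = 0.826 with an estimated correlation). Examples are rpsI (-0.61 ± 0.32), rplM (-0.52 ± 0.31) and rpsO (-0.43 ± 0.26), while rplW had 0.44 ± 0.28. Without the forward array that lacked cadmium, the ribosomal median became 0.15 (adjusted p = 0.599), and the arginine median 0.00 with a mean of -0.14 (adjusted p = 0.916). Without the forward cadmium array neither list passed (adjusted p = 0.706 for each), and without the swapped cadmium array 6 lists passed. Without the swapped array that lacked cadmium both were larger. There 0 of 7 arginine genes were above 0 (median -0.70) and 34 of 40 ribosomal genes below 0 (median -0.44). Each of these omissions leaves 1 condition with a single dye orientation. With no dye term its dye bias then stays in the pH estimate, so these fits do not separate dye from pH. With a dye term the ribosomal call ended (adjusted p = 0.0706 on the same 4 arrays and 0.338 on all 8 arrays), while arginine synthesis passed on the same 4 arrays (adjusted p = 0.0239). Both calls also ended under a loess on intensity alone (adjusted p = 0.310 for each), with medians of -0.55 for arginine and -0.18 for ribosomal genes, and under median centring the ribosomal median was -0.52.

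Single genes at 5 minutes with small p included yhiL (1.35 ± 0.35), yidE (0.83 ± 0.25), bcsZ, an endoglucanase gene of cellulose synthesis (1.06 ± 0.33), yrdD (0.75 ± 0.26) and ybgQ (0.70 ± 0.25). Below 0 were the histidine operon leader hisL (-0.75 ± 0.25), yebV (-1.02 ± 0.34), yjaH (-0.68 ± 0.26), the cold shock gene cspA (-0.66 ± 0.26) and fabA of unsaturated fatty acid synthesis (-0.69 ± 0.27). These 10 had their sign on 4 of 4 arrays. None of 2146 genes passed in limma (smallest adjusted p = 0.9996), and 8 had an unadjusted p under 0.05 where chance gives 107 (7 to 124 over the alternative settings). Without a dye term the dye bias of each pair of arrays stays in the residual, which makes these p-values conservative. The count of 0 therefore does not show that pH had no effect. Adjusted over the list alone, 0 members passed in any list. hdeA had 1.75 ± 1.64, the zinc uptake gene znuA -0.27 ± 0.29 and the chaperonin gene groL 0.01 ± 0.34.

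At 15 minutes, asr had a log2 change of 1.63 ± 0.53 (unadjusted p = 0.0441) and groL 0.84 ± 0.27 (unadjusted p = 0.043), both above 0 on 4 of 4 arrays. Smaller p-values belonged to yggP (1.26 ± 0.25), yjiS (0.88 ± 0.22), ygiM (0.85 ± 0.23) and yceD (0.76 ± 0.22). Below 0 stood yafU (-1.23 ± 0.23), prpR, the activator of propionate use (-1.35 ± 0.34), yidI (-1.59 ± 0.46), yiiG (-1.65 ± 0.49) and ugpE of glycerol phosphate uptake (-0.89 ± 0.27). The phosphate starvation list had 0 of 4 members above 0 (median -0.59) and the flagella and chemotaxis list 11 of 13 (median 0.41). Neither passed (adjusted p = 0.0977 for each in camera, 0.989 with an estimated correlation), while without the swapped cadmium array 3 lists passed. None of 905 genes passed in limma, 18 had an unadjusted p under 0.05 where chance gives 45.3 (2 to 160 over the alternative settings), and adjusted over the list alone 0 members passed.

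The difference between the times asked whether the pH effect at 15 minutes departs from that at 5 minutes. Flagella and chemotaxis genes, which build the swimming motor and its sensory system, shifted up as a list: 10 of 12 members were above 0, with a median difference of 0.55 (adjusted p = 0.0215 in camera; adjusted p = 0.901 with an estimated correlation). fliD, the filament cap, had 0.60 ± 0.27, the export chaperone gene fliT 0.66 ± 0.30, the chemoreceptor gene tap 0.68 ± 0.33 and flhB of the export apparatus 0.45 ± 0.28. The call ended without the forward arrays of 5 or 15 minutes that lacked cadmium (medians 0.43 and 0.27, adjusted p = 0.227 and 0.345), without the swapped cadmium arrays of 5 or 15 minutes (medians 0.36 and 0.16, adjusted p = 0.272 and 0.356) and under print-tip loess (median 0.42, adjusted p = 0.0891). Without the swapped array of 15 minutes that lacked cadmium, 2 lists passed. Single genes above 0 were the arabinose permease gene araH (1.21 ± 0.35), yebV (1.13 ± 0.36), sgcA (0.99 ± 0.33) and the sulfate permease gene cysU (0.78 ± 0.26). Below 0 were yiiG (-1.93 ± 0.40), the outer membrane assembly gene bamC (-2.20 ± 0.56), yedJ (-1.95 ± 0.59), the SOS gene yebG (-1.74 ± 0.54) and yafU (-2.62 ± 0.85), with their sign in 13, 12, 11, 11 and 16 of 16 pairings of arrays. None of 809 genes passed in limma (smallest adjusted p = 0.829), 30 had an unadjusted p under 0.05 where chance gives 40.5 (11 to 138 over the alternative settings), and adjusted over the list alone 0 members passed.

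The interaction asked whether the pH effect differs between cells with and without cadmium. At 5 minutes the highest-placed genes were ccmG of cytochrome c maturation (1.93 ± 0.56), the regulator gene yeiE (1.86 ± 0.55), yjhG (2.06 ± 0.66), panC of pantothenate synthesis (1.60 ± 0.57) and livH of branched-chain amino acid uptake (2.18 ± 0.79). On the other side were waaH, a lipopolysaccharide sugar transferase gene (-3.62 ± 1.17), ygfT (-3.11 ± 1.01), the nitroreductase gene nfsB (-1.68 ± 0.55), rhsD (-1.64 ± 0.58) and yiaM (-1.54 ± 0.58). The NADH dehydrogenase list, the entry complex of respiration, had 5 of 6 members above 0 (median 1.19, adjusted p = 0.310 in camera, 0.989 with an estimated correlation). Without the swapped array that lacked cadmium, 3 lists passed. hdeA had -4.88 ± 3.29, and -4.88 ± 0.87 with all 8 arrays, a dye term and genes missing on some arrays kept, an alternative chosen after seeing the data (adjusted p = 0.401 in limma). None of 2146 genes passed in limma, 10 had an unadjusted p under 0.05 where chance gives 107 (6 to 165 over the alternative settings), and adjusted over the list alone 0 members passed.

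At 15 minutes the interaction gave cspC, a cold shock family gene (2.27 ± 0.50), the ferric enterobactin binding gene fepB (1.42 ± 0.46), the major lipoprotein gene lpp (1.36 ± 0.45), tfaX (1.51 ± 0.52) and the enolase gene eno (1.24 ± 0.44) above 0. Below 0 were yphD (-2.61 ± 0.79), kdsD of lipopolysaccharide core synthesis (-1.30 ± 0.47), ugpE (-1.48 ± 0.55), yiiG (-2.58 ± 0.97) and the secretion gene secF (-1.28 ± 0.49). Copper and silver efflux genes, which export other toxic metals, had 0 of 3 members above 0 (median -1.66), the PhoPQ regulon of low magnesium 0 of 4 (median -0.74) and the iron acquisition list 10 of 12 (median 0.69). Their adjusted p in camera were 0.101, 0.101 and 0.169, and 0.841 for each with an estimated correlation. Without any 1 of 3 arrays (either cadmium array or the swapped one without cadmium) 1 list passed. Of the metal genes fixed in advance, the cadmium exporter gene zntA had 0.80 ± 1.31 and its regulator gene zntR 0.69 ± 0.45. None of 905 genes passed in limma, 5 had an unadjusted p under 0.05 where chance gives 45.3 (1 to 155 over the alternative settings), and adjusted over the list alone 0 members passed. In simulated data neither interaction fit (4 arrays, no dye term) recovered any changed gene, at a log2 size of 4 included, so the counts of 0 from these fits say little.

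The cadmium effect averaged over pH and time compares arrays with each other and does not depend on the dye of either channel. Envelope stress genes rose as a list in camera: all 3 measured members were above 0, with a median log2 change of 0.97 (adjusted p = 0.0364; adjusted p = 0.558 with an estimated correlation). They were rseC of the operon of the envelope stress sigma factor (2.25 ± 0.87), the sigma factor gene rpoE itself (0.97 ± 0.58) and the periplasmic chaperone gene spy (0.53 ± 0.87). Heat shock genes had 6 of 7 members above 0 (median 0.57), among them groL (1.75 ± 0.87) and dnaK (1.04 ± 1.01), and iron acquisition genes 11 of 12 below 0 (median -0.24), among them exbD (-1.01 ± 0.40) and exbB (-0.87 ± 0.45). Neither list passed (adjusted p = 0.0575 for each in camera). The heat shock direction differed between the times. At 5 minutes, with 15 members measured, 11 lay below 0 (median -0.42), and at 15 minutes 6 of 8 lay above 0 (median 0.40). The envelope call ended without the forward cadmium arrays of 5 or 15 minutes (medians 0.88 and 0.98, adjusted p = 0.0500 and 0.263, 2 of 3 members above 0 in the latter), the swapped cadmium array of 5 minutes (median 0.93, adjusted p = 0.0674) and the swapped arrays of 5 or 15 minutes without cadmium (medians 0.58 and 1.00, adjusted p = 0.151 and 0.374). Without the swapped cadmium array of 15 minutes 5 of 5 members were above 0 (median 1.44, adjusted p = 8.4e-05), and without both swapped cadmium arrays, an alternative chosen after seeing the data, 8 of 9 (median 0.81, adjusted p = 0.00859). Without the forward array of 15 minutes that lacked cadmium, 4 lists passed. With the dimmest genes left out too few members remained to test.

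Single genes above 0 with cadmium over all conditions were arsR, the repressor of arsenic resistance (1.20 ± 0.50), ydbL (1.81 ± 0.77), tusE of transfer RNA thiolation (1.29 ± 0.58) and yjbJ (1.01 ± 0.48). Below 0 were the urate transporter gene uacT (-1.45 ± 0.45), ybcV (-1.31 ± 0.42), the ribosomal protein gene rpsD (-2.49 ± 0.83), the transketolase gene tktA (-1.18 ± 0.39) and hycG of a hydrogenase (-1.20 ± 0.41). Those above 0 had their sign in 14 of 16 pairings of arrays, and those below 0 in 12, 11, 14, 8 and 10 of 16, in that order. For cadmium these pairings were counted on mean intensities before Aquantile normalisation. They therefore carry the brightness of whole arrays and do not measure agreement on the tested change. zntR, which senses zinc and cadmium, had -0.15 ± 0.37. None of 809 genes passed in limma, 16 had an unadjusted p under 0.05 where chance gives 40.5 (9 to 37 over the alternative settings), and adjusted over the list alone 0 members passed.

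At 5 minutes of cadmium the genes with the smallest p were ycjQ (3.73 ± 0.62), aroH of aromatic amino acid synthesis (3.16 ± 0.67), ispB, an isoprenoid synthase gene (3.13 ± 0.69), the cell wall transpeptidase gene ldtE (2.91 ± 0.75) and arsB, the arsenite efflux pump (2.75 ± 0.76). Below 0 were yqjK (-2.97 ± 0.67), yhiN (-2.82 ± 0.69), yqiA (-2.67 ± 0.70), the glycogen-related gene glgS (-2.96 ± 0.82) and nagB of amino sugar use (-2.45 ± 0.68). Each had its sign in 4 of 4 pairings of arrays, counted before Aquantile normalisation and so mixed with the brightness of whole arrays. Zinc and cadmium transport genes had 5 of 8 members below 0 (median -1.27), among them znuB of zinc uptake (-2.63 ± 0.82), znuA (-1.28 ± 0.71) and the metal exporter gene fieF (-1.50 ± 0.83), while zur, the repressor of zinc uptake, had 2.26 ± 1.60. Colanic acid genes, which make a capsule, had 9 of 9 above 0 (median 0.57), and envelope stress genes 7 of 8 (median 0.71). Their adjusted p in camera were 0.260, 0.195 and 0.260, and 0.928 for each with an estimated correlation. Without the swapped array that lacked cadmium, 5 lists passed. None of 2146 genes passed in limma (smallest adjusted p = 0.937), 100 had an unadjusted p under 0.05 where chance gives 107 (29 to 213 over the alternative settings), and adjusted over the list alone 0 members passed. Without variance moderation, 1 gene (ycjQ) passed.

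At 15 minutes of cadmium rseC had 3.10 ± 1.08, the ribosomal protein gene rpmF 1.97 ± 0.69, the glutaredoxin gene grxC 2.44 ± 0.85, secF 1.75 ± 0.63 and ybiT 1.71 ± 0.62. Below 0 were the ribosomal protein genes rplU (-3.28 ± 0.87) and rpsA (-2.17 ± 0.67), the channel gene mscK (-2.19 ± 0.66), yebV (-1.71 ± 0.55) and aroM (-1.51 ± 0.49). Of these, rpsA, yebV and aroM had their sign in 3 of 4 pairings of arrays, again counted before Aquantile normalisation. Envelope stress genes had 4 of 4 members above 0 (median 0.91) and ATP synthase genes 5 of 5 (median 0.91), with adjusted p of 0.135 and 0.332 in camera and 0.940 for each with an estimated correlation. Without the swapped cadmium array, 8 lists passed. zntA had 0.16 ± 1.03, zntR -0.81 ± 0.50 and groL 2.39 ± 1.31. Some lists changed direction between the times. At 15 minutes colanic acid had 0 of 3 members above 0 (median -0.15) and zinc and cadmium transport 3 of 4 (median 0.46). ATP synthase had 4 of 5 members below 0 at 5 minutes (median -1.41). None of 905 genes passed in limma, 20 had an unadjusted p under 0.05 where chance gives 45.3 (8 to 60 over the alternative settings), and adjusted over the list alone 0 members passed.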

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

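Of the tests in this part, those on the ribosomal protein genes, on the pH effect against the dye coefficient, on the splits for pH and on neighbouring genes over more pairs were chosen only after the result was seen.

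The flagella and chemotaxis list differed between the pH effects at 15 and 5 minutes, with an adjusted p of 0.0215 in camera. With an estimated correlation, a version that hardly any list could pass, it was 0.901. The catalase gene katG lay on one side of 0 on every measured array of 15 minutes and on the other at 5 minutes, with a difference of 1.10 that was not tested. Time is mixed with cadmium there: both arrays at 5 minutes lacked it (-0.12 and -0.87), while at 15 minutes cadmium arrays gave 1.10 and 0.58 and the array without it 0.13. In the chosen name order, spots named as random negative controls exceeded the quality filter at a median of 20.8% over arrays, and unnamed spots at 45.4%, against 0.930% for blank spots. These control names are as open as the gene names: with spots reversed within blocks and the blocks as listed, or with only block rows reversed, 0 of the 1150 random control spots are the same, and with only block columns reversed 1148 are. The share above the filter is 34.3% in each of the former orders, 20.8% in the last and 36.7% as listed.

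The first pattern is that Cy5 over Cy3 ratios of genes repeated across both dye orientations, so that pH ratios of opposite arrays ran against each other. In the chosen name order, random negative control features repeated the ratio with r = 0.477 (95% interval 0.364 to 0.588) against 0.567 for K-12 genes and 0.625 (0.572 to 0.672) for unnamed features, as a dye bias would give, but which spots are controls rests on that open order, so a probe-specific dye bias stays a candidate explanation. Mislabelled swaps stayed open too: among 97 pairs of neighbouring genes, the part of the ratio that keeps its dye sign correlated at 0.0520 (-0.149 to 0.260) and exceeded the part that turns with the labels by -0.200 (-0.484 to 0.0777), and over 1187 pairs from genes missing on some arrays the values were 0.105 and 0.0400 (-0.0373 to 0.120), the opposite order. asr (forward mean 3.43, swapped 0.71) and cpxP (-2.54 and -0.40) kept their sign in both orientations, which exchanged labels would turn, while hdeA did not (-1.56 and 3.87). These means cover unlike conditions, since each gene lacks some arrays. cpxP has no value on the swapped cadmium arrays. Without cadmium it had -0.45 (5 minutes) and -1.86 (15 minutes) forward, and -0.56 and -0.24 swapped. So few named genes decide nothing. No biological explanation was tested.

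The second pattern is that 7 of the 10 genes with the smallest p for the average pH effect also passed for the dye, while malQ, glnH and smf did not (Cy5 over Cy3 -0.43, 0.47 and -0.33). The pH effect and the dye coefficient correlated at -0.657 (-0.727 to -0.575) over genes, but they are the difference and the sum of the same means, so this restates that forward and swapped ratios differ in spread (SD 0.73 and 1.29). A dye bias of unequal size in the orientations is a candidate explanation that this value cannot decide, and a response to pH stays open beside it. For the count of 0 genes past the threshold, 32 of 32 splits of the arrays that could be fitted gave as many for pH (highest other 11) and 34 of 34 for cadmium on mean intensities (highest other 15), which a count of 0 makes certain. At unadjusted p under 0.05, 5 of 32 splits gave at least the 66 genes of pH (highest other 118) and 27 of 34 at least the 22 of cadmium (highest other 126), so chance cannot be excluded for either, and splits with many more calls point to other structure among the arrays.

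The third pattern is that spot brightness did not go with the gene names in the listed order, and names read from the opposite corner of the grid are a candidate explanation. The ribosomal percentile of 71.2 against 49.7 is the highest of 13 orders, but these genes helped to choose the order, so it is no independent evidence. A test written beforehand on 24 ATP synthase and citric acid cycle genes that played no part in the choice gave 51.1 against 45.6, short of the 60 that had been required, and other orders reached up to 56.5. A second, on the brightness of neighbouring genes, gave a correlation of 0.232 against 0.222, where the listed order would have had to stay under 0.1. Pairs at least 200 bp apart gave 0.130 against 0.211, a comparison for which no bound had been set. The order of the print blocks, and with it every gene name, therefore stays open.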

How the results depend on the processing

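The settings with names in the listed order, with genes missing on some arrays kept and without both dye-swapped cadmium arrays were chosen after seeing the data. Of 331 counts recomputed, 275 stayed within 1.5 times the reported count and 56 moved. Counts of 0 that remained 0 are among the 275, and every reported gene count was 0, so this tally is no measure of stability. Of 3139 values of named genes, 3013 kept their direction, 126 took the other, 5 passed the threshold and 0 passed in the other direction. Some settings could not turn a direction: the variance model, and a dye term where every condition has both orientations. Gene counts moved from 0 to 2 for the average pH effect with uncorrected foreground intensities, with median centring and with the authors' processed values (515 probes, unnamed), and to 1 for cadmium at 5 minutes without variance moderation. The 0 elsewhere comes from limma, with 1 to 213 genes at an unadjusted p under 0.05 depending on comparison and setting. The number of genes fitted also depends on the setting, with 2481 where genes missing on some arrays were kept. A high count is therefore not an excess over the chance value of the reported fit. No paired analysis was possible by culture because the labels carry no replicate numbers. Dye orientation was fitted as a term instead, on all 8 arrays and, as an alternative, on 4. Leaving out the spot marks removed no spot, so that setting says nothing. Lone arrays left by an omission were assumed to vary like the other conditions. Signal over background ran from 2.08 to 12.8 in Cy3 and from 2.29 to 14.5 in Cy5.

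Counts of lists moved more. With an estimated correlation 0 lists passed in each comparison. For pH at 5 minutes (2 lists reported) the count was 0 under loess on intensity, print-tip loess, both fits of all 8 arrays and names in the listed order, 1 under median centring (ribosomal proteins) and 1 (arginine synthesis) with a dye term on 4 arrays and without the dimmest genes. For 15 against 5 minutes (1 reported) it was 0 under print-tip loess, without the dimmest genes, with names in the listed order and without both swapped cadmium arrays, and 2 under median centring. For cadmium over all conditions (1 reported) it was 0 without the dimmest genes and with names in the listed order, 3 with uncorrected intensities and with median scaling, 2 with quantile normalisation and 7 without both swapped cadmium arrays. From a reported 0, it was 1 for pH at 15 minutes with all 8 arrays and no dye term, for the interaction at 5 minutes under median centring, for cadmium at 15 minutes under quantile normalisation and for the average pH effect without both swapped cadmium arrays. Leaving out each array in turn gave 0 to 6 lists for pH at 5 minutes, 0 to 3 for pH at 15 minutes, 0 to 3 for the interaction at 5 minutes, 0 to 1 for that at 15 minutes, 0 to 2 for the difference between times, 0 to 4 for cadmium over all conditions, 0 to 5 at 5 minutes and 0 to 8 at 15 minutes. The highest of these came without the swapped cadmium array of the time in question for pH at 5 and 15 minutes and for cadmium at 15 minutes. In the pH and interaction fits of 4 arrays an omission leaves 1 condition with a single dye orientation. There, without a dye term, dye bias stays in the estimate. The cause of these counts was not tested. Directions of the 4 reported lists: arginine synthesis kept its direction in 12 of 13 settings (passing in 7), ribosomal proteins in 13 of 15 (passing in 6), flagella in 18 of 18 (passing in 10) and envelope stress in 18 of 18 (passing in 13). Within-array normalisation, spot marks and the dye term do not reach the mean intensities of the envelope test. Loess on intensity, print-tip loess, median centring, no filter on spot marks and no dye term therefore repeat its reported value. These repeats are counted among its 13 passing settings and are no sign of stability. With names in the listed order the flagella median was -0.04. These list tests under other settings were run when the reported lists were known.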

Other observations

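The test in this part with names in the listed order, and the fit that kept genes missing on some arrays, were chosen only after the result was seen.

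When genes missing on some arrays were kept, further genes joined asr near the top of the average pH effect without passing. pspE, a periplasmic rhodanese gene, had a log2 change of 1.52 ± 0.25 (SE), yjaB, an acetyltransferase gene, 2.27 ± 0.37, cpxP -2.16 ± 0.31 and cusA, the inner membrane pump of copper and silver efflux, -1.21 ± 0.21. Their adjusted p in limma was 0.647 for each. asr had 3.47 ± 0.37 at 5 minutes and 1.63 ± 0.29 at 15 minutes, and cusA -2.31 ± 0.34 at 15 minutes. The cadmium condition of 5 minutes holds a single array for asr (6.31, forward), and both cadmium conditions a single array each for cpxP, so these SEs rest on the spread in the other conditions. These genes were chosen after their values were seen.

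Cold shock genes had 3 of 3 members above 0 for the difference between times (median 0.75, adjusted p = 0.128 in camera, 0.901 with an estimated correlation). Histidine synthesis genes had 4 of 4 above 0 both for the interaction at 5 minutes (median 0.98, adjusted p = 0.442) and for cadmium at 5 minutes (median 0.99, adjusted p = 0.268). Arginine synthesis genes had 7 of 7 above 0 for the interaction at 5 minutes (median 0.58, adjusted p = 0.492).

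Under the listed names the feature called asr was measured on 4 arrays and lay above 0 on 4 of them, and its pH effect could not be fitted. The forward arrays averaged 3.43 for asr in the chosen order and the swapped ones 0.71. The forward mean includes cadmium at 5 minutes (6.31), where the swapped array has no value. Forward and swapped arrays gave 2.45 and 0.56 without cadmium at 5 minutes. At 15 minutes they gave 1.65 and 0.72 with cadmium and 3.30 and 0.84 without. In these conditions the size of asr differed between the orientations while its sign did not.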
